A study of Arabidopsis thaliana with 48 samples.

How the data were processed

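Transcript levels were measured in Arabidopsis thaliana rosette leaves on an Agilent oligonucleotide array with the 2 dyes Cy3 and Cy5. The 48 samples covered 4 genotypes: the wild type Col-0, the mutants med16 and med8, which lack subunits of the Mediator complex that links transcription factors to RNA polymerase II, and the mutant elp2, which lacks a subunit of the Elongator complex. Per the labels, plants were inoculated with the necrotrophic fungus Sclerotinia sclerotiorum and sampled on days 0, 1, 2 and 4 (days after inoculation, dpi), with leaves of 8 to 12 plants in a sample and 3 samples in each of the 16 groups. The 0 dpi samples were control leaves, the 1 dpi samples the inoculated leaves, and the 2 and 4 dpi samples the upper leaves that had not been inoculated. No mock-inoculated group was among the samples, so a change against 0 dpi also holds whatever changed with time, wounding or leaf position.

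Each of the 24 arrays held 2 samples of the same time and replicate number, either Col-0 with elp2 or med16 with med8. Col-0 and med16 were labelled with Cy3 in replicate 1 and with Cy5 in replicates 2 and 3, and elp2 and med8 the other way round. The authors quantified the scans with Agilent Feature Extraction 10.1.1.1, per the submitters' processing notes. The background correction, the normalization and the genome build of the probes are not given in the sources used here. The deposited values are log2 intensities, 1 column for each sample, and the authors had already brought the 48 columns to nearly the same distribution: the column medians lay between 7.96 and 7.97. They were used as deposited, with no further scaling or filter. The highest value was 18.3 log2, and values near it recurred. In all 3 Col-0 samples at 1 dpi, 1 probe was at 18.1 log2 (SD 0). Levels and folds that reach the top of the scale are therefore not exact. The table held 33200 rows, of which 33143 were plant probes and 57 were control spots.

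The files used here do not pair the probes with genes. All values are therefore per probe, and several probes can belong to 1 gene. For the same reason the 23 gene lists fixed before the data were examined, the probes of the 3 mutated genes and the planned averaging over the probes of a gene could not be tested, and the labels of the mutants were not checked against their own transcripts. The rule for named genes, fixed before the data were examined, took the largest changes among called genes with a symbol whose samples did not overlap between the groups. It was applied to probes without the condition of a symbol, and the text names only the 2 probes that rose and the 2 that fell most in Col-0 at 1 dpi. The order of the rising probes is that of the deposited values, since other probes at the top of the scale may have risen as much. For other comparisons the size of the largest changes is given without a name.

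Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with a mean for each of the 16 groups and a term for the dye was fitted to all 48 samples together, with the array as a random block (consensus correlation 0.465) and a variance trend in the empirical Bayes step, which left 31 residual degrees of freedom. A probe is said to be called where the Benjamini-Hochberg adjusted p within its comparison was below 0.05. Counts are also given for called probes with at least a 2-fold difference (1 on the log2 scale). The 22 comparisons comprised 16 between pairs of groups and 6 tests of whether the change of a mutant differed from that of Col-0, at 1 dpi against 0 dpi or for the mean of 2 and 4 dpi against 0 dpi. Col-0 and elp2 shared arrays, as did med16 and med8, and their differences had smaller standard errors, so genotypes are compared by their 2-fold counts. The number of arrays, 3 samples in each group, limits the precision.

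The labels call the 3 samples of a group biological replicates, but the design text can also be read as equal amounts of RNA taken from the 3, and their values lay close together: over the 16585 probes with a mean above 8 log2 the median standard deviation (SD) within a group was 0.103, and the lowest correlation between replicates was 0.988. The p-values measure only the spread between these samples. The background limit, 6.64 log2, was the mean of the negative-control spot over all samples plus 3 SD. Where the lower group lay below that limit, the fold was computed against the limit and is given as "at least". In at least 1 group, 84.2% of the probes lay above it. Permutation tests of 3 samples against 3 were exact and 2-sided and cannot give a p below 0.1.

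The fit was tested on simulated data with the same arrays and dyes, in which 68 probes were changed by 0.25 log2 and 66 each by 0.5 and by 1. In the comparison of med16 with Col-0 at 1 dpi, 97.0% of the changes of 1 log2 were called, 48.5% of those of 0.5 and 8.82% of those of 0.25, among 33143 probes. For elp2 against Col-0 at 1 dpi the shares were 100%, 72.7% and 32.4%. With so few changed probes the adjustment is stricter than in the data, where 12988 probes were called for med16. These shares therefore do not give the sensitivity of the real comparisons. Comparisons that share control libraries were set against 20 simulated data sets without any effect.

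The replicate numbers come from the labels. Whether they pair samples was judged from correlations, not from calls. After removal of group means and dye, samples of the same number correlated by over 0.1 in each of the 3 pairs in 12 of the 16 comparisons of 2 groups; the exceptions were Col-0 at 2 and at 4 dpi against 0 dpi, med8 against Col-0 at 0 dpi and elp2 against Col-0 at 1 dpi. The lowest of these correlations was -0.584, in Col-0 at 4 dpi against 0 dpi. Same-numbered Col-0 samples of 0 and 1 dpi thus varied together, and those of 0 dpi and of 2 or 4 dpi did not. Among the 12 comparisons, elp2 against Col-0 at 0, 2 and 4 dpi and med16 against med8 at 1 dpi share arrays. Over all samples the mean correlation was 0.465 on the same array and 0.0227 for the same number on other arrays. That mean averages positive correlations with negative ones such as -0.584, so it does not show that same-numbered samples were unpaired. The rest of the 12 comparisons do not share arrays, for example med16 against Col-0 at 2 dpi (0.727, 0.427 and 0.335). Pairing by number thus had support within some times and pairs of times, and not over all samples. The main fit holds no replicate block. A block within 0 to 1 dpi and within 2 to 4 dpi raised the calls of med8 at 1 dpi from 4216 to 6412.

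The alternatives planned before the data were examined were a fit without the dye, without the array block, with the replicate block, with only the compared groups, with quantile normalization, without the 8286 dimmest probes, without the variance trend, and with each library left out in turn. Chosen after seeing the data were a replicate block within each pair of times, the removal of the 0 dpi array with med16 and med8 of replicate 1, and a scaling of each library to 10 spike-in spots. These spots detect RNA added at labelling, and the offset of a library is the mean over the spots of its difference from all libraries of the same dye. Slopes and positions along the Col-0 response were also chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.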

Results

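The data comprised 48 leaf samples of Arabidopsis, 3 for each of 4 genotypes at 0, 1, 2 and 4 dpi with Sclerotinia sclerotiorum, a fungus that kills host tissue and feeds on it. Of 33143 plant probes, 27919 lay above the background limit in at least 1 group. The first principal component held 52.0% of the variance, and 99.97% of its variance lay between the 16 groups. The comparisons addressed how wild type leaves respond to the fungus at the site of inoculation and in upper leaves, and how this response differs without the Mediator subunits MED16 and MED8 or the Elongator subunit ELP2.

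In wild type leaves, inoculation was followed by a change in about as many probes upward as downward. At 1 dpi, 3061 probes were at least 2-fold higher and 3447 at least 2-fold lower than at 0 dpi. In the 4 probes named here the 3 samples of the groups did not overlap, which the rule for naming required. The probe A_84_P867721 rose 1060-fold, from 6.76 ± 0.094 to 16.8 ± 0.277 log2 (SD, n = 3; log2 fold change 10.05, standard error (SE) 0.464, adjusted p = 1.35e-20). The probe A_84_P310613 rose 1014-fold to 17.8 ± 0.103 (SE 0.743, adjusted p = 1.63e-14). Among the probes that fell, A_84_P802547 went from 15.1 ± 0.0328 to 7.68 ± 0.017 (log2 fold change -7.45, SE 0.068, adjusted p = 1.29e-41) and A_84_P569474 from 14.7 ± 0.226 to 8.42 ± 0.0788 (log2 fold change -6.28, SE 0.106, adjusted p = 1.82e-33). At any size, 16747 probes were called, 50.5% of those tested. The 3 samples of each group did not overlap in 54.4% of the probes, where chance gives 10%.

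**Figure D1:**
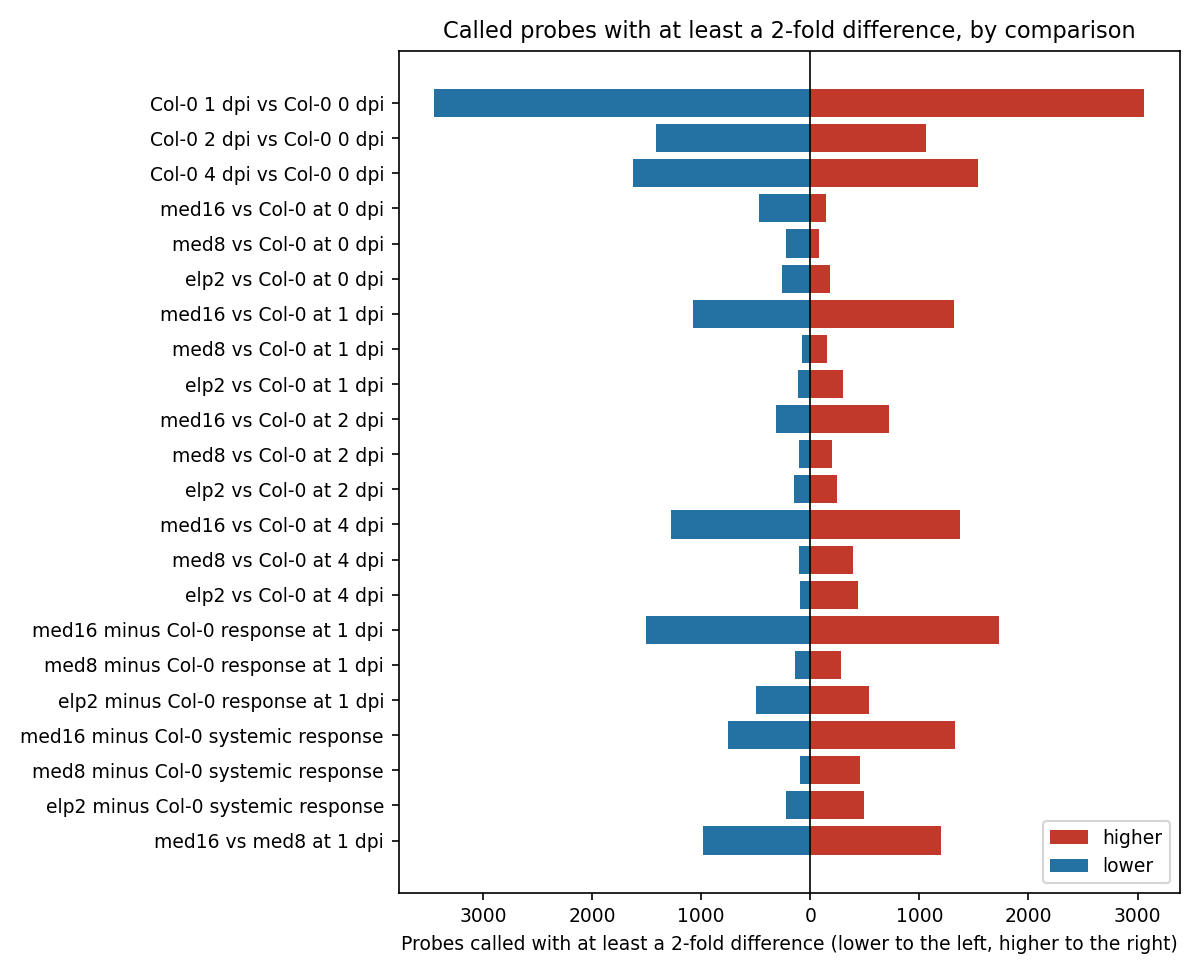
Bars give the number of called probes with at least a 2-fold difference (x axis) in each comparison (y axis), higher to the right and lower to the left. The longest bars are those of Col-0 at 1 dpi, with 3061 higher and 3447 lower, and the 2 bars of med16 together are longer than those of med8 or elp2 in each matching comparison.

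Upper leaves that had not been inoculated changed as well, in fewer probes. At 2 dpi, 1057 probes were at least 2-fold higher and 1417 lower than at 0 dpi, and at 4 dpi 1540 were higher and 1623 lower. Of these, 660 of the higher and 943 of the lower at 2 dpi, and 975 of the higher and 1089 of the lower at 4 dpi, had moved 2-fold in the same direction in inoculated leaves. Independent lists would share 97.6, 147, 142 and 169 probes. Changes at 2 and 4 dpi resembled each other: 956 probes were higher at both times and 1183 lower, and only 2 moved in opposite directions. A_84_P310613 stayed nearly as high in upper leaves as in inoculated ones (17.2 ± 0.12 at 2 dpi and 17.4 ± 0.169 at 4 dpi), all near the top of the scale. A_84_P867721 reached 13.2 ± 0.035 and 13.7 ± 0.0488. A_84_P802547 fell to 9.11 ± 0.158 and 9.03 ± 0.0397, and A_84_P569474 to 11.2 ± 0.143 and 9.51 ± 0.0409.

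In total, 12178 probes were called at 2 dpi and 13378 at 4 dpi. The 3 comparisons share the 0 dpi libraries, and part of the overlap may come from these shared controls. Between 1 and 4 dpi the covariance of the fold changes across probes was 0.372, against 0.0102 simulated with no effect. The correlation was 0.549. Noise alone gave 0.499, which is no baseline for a correlation in data with effects. Scaling the libraries to the spike-in spots moved the median of all probes up by 0.126 log2 at 2 dpi and 0.347 at 4 dpi, so that 68.2% of 9925 and 86.3% of 19302 called probes were higher, against 54.9% and 53.1% as deposited. At least 2-fold, the scaled counts were 1468 higher and 1146 lower at 2 dpi, and 3124 and 947 at 4 dpi. Such a shift applies to each statement on direction, which holds relative to the middle of all probes.

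In control leaves at 0 dpi the mutants differed from Col-0 in few probes by 2-fold, and more of these were lower than higher. In med16, 143 probes were at least 2-fold higher and 465 lower, in med8 80 and 223, and in elp2 184 and 258. The largest differences were 17.1-fold higher and 28.3-fold lower in med16, 7.63-fold higher and at least 7.47-fold lower in med8, and 9.12-fold higher with a reference above background and 9.98-fold lower in elp2. The Mediator mutants shared 135 of the lower probes and 31 of the higher ones, where independent lists would share 3.13 and 0.345. Med16 and elp2 shared 65 and 22, against 3.62 and 0.794. The mutants were compared with the same Col-0 libraries. Med16 and med8 also shared arrays, and med16 and elp2 did not, so these overlaps are not a like-for-like contrast. Over all probes the covariance of the med16 and elp2 differences was 0.0253, against 0.00547 simulated with no effect. That of the med16 and med8 differences was 0.0573, against 0.0150 simulated with no effect. Their correlation was 0.611. Noise alone gave 0.730, which is no baseline for a correlation in data with effects.

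At any size, 6320 probes were called in med16, 5450 in med8 and 9618 in elp2. After spike-in scaling the counts were 3026, 2312 and 5650, of which 28.3%, 57.4% and 20.6% were higher, against 51.5%, 50.6% and 50.6% as deposited. At least 2-fold, the scaled counts were 94 higher and 566 lower in med16, 96 and 180 in med8, and 135 and 393 in elp2. Without the array with med16 and med8 of replicate 1, 145 probes were at least 2-fold higher and 243 lower in med8. The med16 library of replicate 1 stood apart: of 140 probes induced by over 5 log2 in Col-0 at 1 dpi, 16 were over 2 log2 higher there than in both other replicates, while no other library had more than 1 such probe. A_84_P310613 was at 12.1 log2 in that library and below the background limit of 6.64 in the other 2. With this library the probe was not called between med16 and Col-0 at 0 dpi (0.59 log2, SE 0.743, adjusted p = 0.706), and without it the probe was called lower in med16 (adjusted p = 0.00352), with a difference of -1.15 or lower when computed against the limit. In that fit the probe was also called lower in med8 (-1.13, adjusted p = 0.00579) and elp2 (-1.22, adjusted p = 2.47e-05). Both lay below the limit, so the lower level was not particular to med16.

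In inoculated leaves at 1 dpi, med16 differed from Col-0 in 1315 probes at least 2-fold higher and 1073 lower, med8 in 153 and 71, and elp2 in 297 and 111. The lower probes of med16 were largely probes that rose in Col-0: of the 3061 that rose 2-fold there, 702 were 2-fold lower in med16 and 314 higher, against 53 and 11 in med8 and 82 and 54 in elp2. Of the 3447 that fell in Col-0, 231 were higher in med16, 36 in med8 and 135 in elp2. The Col-0 libraries at 1 dpi enter both sides of these counts. The largest differences in med16 were 48.2-fold higher and, for A_84_P310613, 173-fold lower. The next largest fall, 100-fold, was in a probe at the top of the scale in Col-0 (18.1 log2, SD 0), so this order is uncertain. A_84_P310613 was at 10.3 ± 0.565 in med16 against 17.8 ± 0.103 in Col-0 (n = 3, log2 difference -7.44, SE 0.743, adjusted p = 1.16e-10). A_84_P867721 was lower in med16 too (13.1 ± 0.254, log2 difference -3.75, SE 0.464, adjusted p = 1.62e-08). In med8 A_84_P310613 and A_84_P867721 were near the Col-0 level, at 17.7 ± 0.163 and 16.7 ± 0.234. In elp2, A_84_P310613 was at 15.1 ± 1.05 (log2 difference -2.79, adjusted p = 9.52e-05). Direct comparison of the Mediator mutants, which share arrays, gave 1200 probes at least 2-fold higher in med16 than in med8 and 979 lower.

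**Figure D2:**
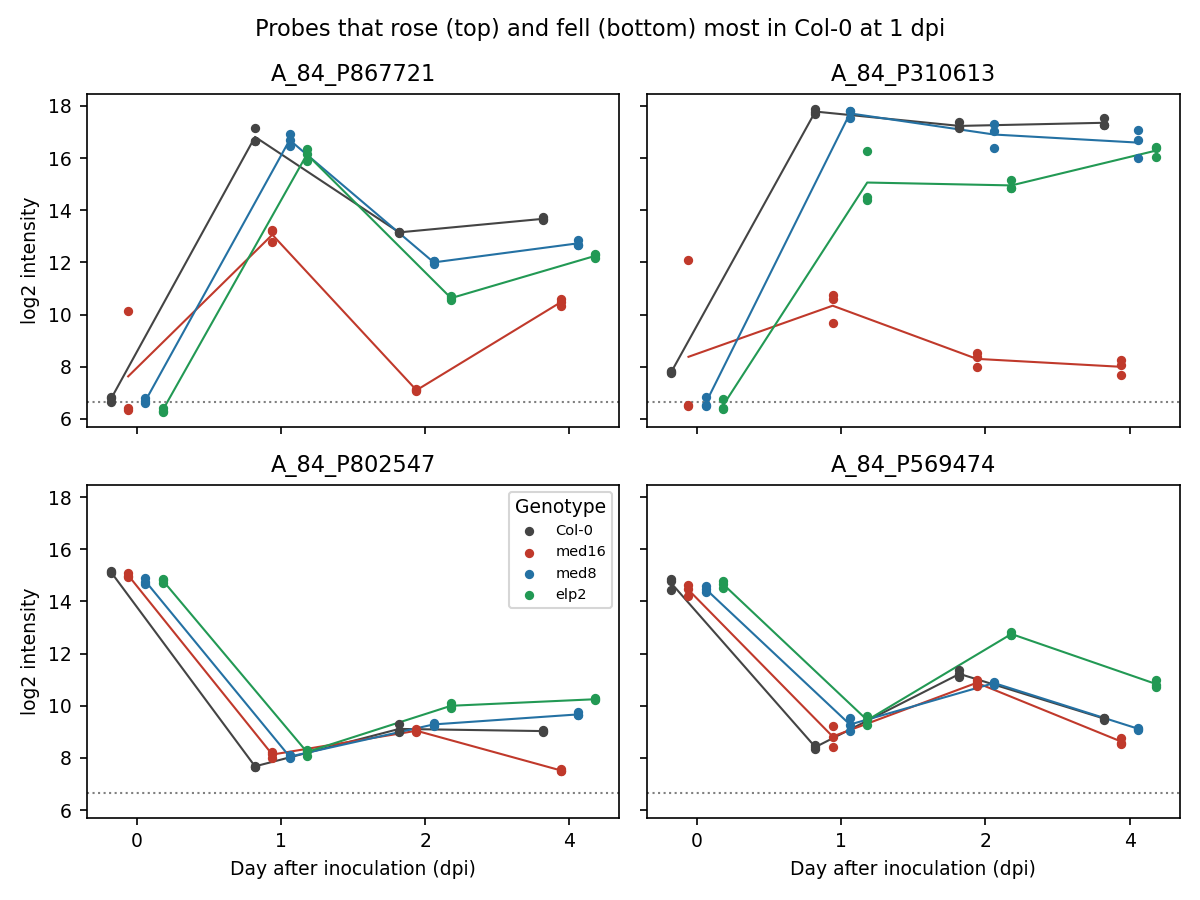
Points are the log2 intensity (y axis) of each library by day after inoculation (x axis) for the 2 probes that rose and the 2 that fell most in Col-0 at 1 dpi. Colours mark genotypes, lines join group means, and the dotted line is the background limit of 6.64. In med16, A_84_P310613 lies at 10.3, 8.30 and 8.00 at 1, 2 and 4 dpi, below the other genotypes, and 1 library lies high at 0 dpi.

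At any size, 12988 probes were called in med16, 4216 in med8, 9797 in elp2 and 15554 between med16 and med8 at 1 dpi. Without the Col-0 1 dpi library of replicate 1, the 2-fold counts of med8 were 142 higher and 108 lower. With only the compared groups in the fit, med8 had 1234, and with a replicate block within 0 to 1 dpi and within 2 to 4 dpi it had 6412. After spike-in scaling 28595, 4142, 9778 and 25880 probes were called, of which 4.24%, 8.33%, 93.0% and 7.03% were higher, against 45.8%, 46.8%, 48.3% and 46.7% as deposited. At least 2-fold, the scaled counts were 380 higher and 6687 lower in med16, 81 and 205 in med8, 590 and 53 in elp2, and 520 and 3372 between med16 and med8. The spike-in spots of the med16 libraries at 1 dpi were brighter by 0.756 ± 0.104 log2 than the mean of all libraries of the same dye, and those of Col-0 by 0.0536 ± 0.0312 (n = 3 each; exact permutation p = 0.1, the smallest possible). A_84_P802547 and A_84_P569474, called slightly higher in med16 than in Col-0 as deposited (0.45 and 0.41 log2), were lower after this scaling (-0.25 and -0.30).

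**Figure D3:**
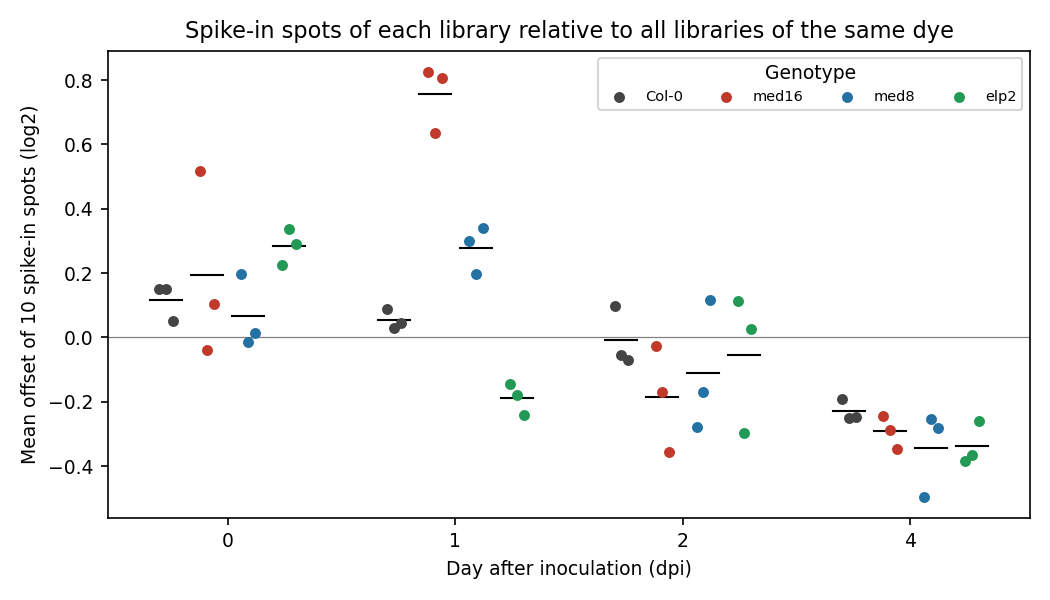
Points are the mean log2 offset of 10 spike-in spots (y axis) in each library by day after inoculation (x axis), relative to all libraries of the same dye. Colours mark genotypes and lines the group means. The 3 med16 libraries at 1 dpi lie between 0.636 and 0.825, and the Col-0 libraries at 1 dpi between 0.0288 and 0.0886.

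The local response itself, the change from 0 to 1 dpi within a genotype, differed most from Col-0 in med16: 1732 probes changed at least 2-fold more upward than in Col-0 and 1508 at least 2-fold more downward. The counts were 284 and 135 in med8 and 537 and 500 in elp2. To describe each mutant on probes chosen without its own or the Col-0 values, probes were taken that changed 2-fold in the same direction in the other 2 mutants. Of 1895 such rising probes, 513 rose less in med16 than in Col-0, 791 rose more and 591 were not called. Of 2340 falling probes, 576 fell less and 682 fell more. Where the difference was at least 2-fold, 253 rose less and 417 more, and 207 fell less and 130 more. In elp2, 1148 of 2657 falling probes fell less and 320 more, and among 1954 rising ones 607 rose less and 440 more. With at least a 2-fold difference these were 141 and 32 falling and 74 and 103 rising probes. In med8 most members were not called: 1451 of 1955 rising and 1748 of 2252 falling probes. Of the others, 290 rose less and 214 more, and 360 fell less and 144 more. With at least a 2-fold difference these were 64 and 50 rising and 47 and 7 falling probes.

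The correlation of the med16 and Col-0 changes over its 1895 rising probes, which are not independent replicates, was 0.653. Over their own sets of 1955 and 1954 rising probes it was 0.942 for med8 and 0.923 for elp2. The last 2 sets require a 2-fold rise in med16 and that of med16 does not, so the 3 correlations are not a like-for-like contrast. In the med16 set the mean rise was 2.76 ± 0.0607 log2 in med16 and 2.55 ± 0.0266 in Col-0 (n = 3, exact permutation p = 0.1), an order that turned after spike-in scaling (2.19 and 2.61). In elp2 it was 2.37 ± 0.0203 against 2.40 ± 0.0294 in Col-0 (exact permutation p = 0.3), which turned as well (2.84 and 2.46). The mean fall in med16 was -1.91 ± 0.00851 against -1.92 ± 0.0131 (exact permutation p = 0.2), and after scaling -2.47 and -1.86. The mean fall in elp2 was -1.57 ± 0.0185 against -1.80 ± 0.013 in Col-0 (exact permutation p = 0.1), and after scaling -1.10 and -1.73. At any size the difference of the responses was called in 11153 probes for med16, 3115 for med8 and 9861 for elp2. After scaling these were 23262, 2424 and 14013, of which 6.22%, 12.1% and 94.4% were higher, against 45.1%, 51.7% and 50.1%. At least 2-fold, the scaled counts were 696 more upward and 6619 more downward for med16, 143 and 366 for med8, and 1728 and 119 for elp2. For med8 the replicate block within the 2 pairs of times gave 4862. The difference of the responses of A_84_P310613 was -8.03 log2 in med16 (SE 1.05, adjusted p = 7.15e-08). Without the med16 0 dpi library of replicate 1 it was still called (adjusted p = 6.36e-14), but the other 2 libraries lay below the background limit, and against that limit the difference is no more negative than -6.29.

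In upper leaves, med16 again differed from Col-0 in more probes than the other mutants. At 2 dpi, 719 probes were at least 2-fold higher and 312 lower in med16, 201 and 106 in med8, and 244 and 152 in elp2. At 4 dpi the counts were 1368 and 1278 in med16, 391 and 104 in med8, and 441 and 92 in elp2. A_84_P310613 was at 8.30 ± 0.269 and 8.00 ± 0.292 in med16 at 2 and 4 dpi, against 17.2 ± 0.12 and 17.4 ± 0.169 in Col-0 (log2 differences -8.93 and -9.36, SE 0.743, adjusted p = 2.7e-12 and 2.81e-13). It was at 16.9 ± 0.473 and 16.6 ± 0.543 in med8, and at 15.0 ± 0.182 and 16.3 ± 0.216 in elp2. A_84_P802547, which had fallen in Col-0, was lower still in med16 at 4 dpi (7.52 ± 0.0371 against 9.03 ± 0.0397, log2 difference -1.51, adjusted p = 2.79e-20) and higher in elp2 (10.3 ± 0.0361, log2 difference 1.24, adjusted p = 4.75e-21).

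Among probes that fell in upper leaves of Col-0, more were higher than lower in the mutants than in Col-0 at the same time. Of 1417 probes that fell 2-fold in Col-0 at 2 dpi, 283 were 2-fold higher in med16 than in Col-0 and 34 lower, 115 and 10 in med8, and 78 and 12 in elp2. At 4 dpi, of 1623 such probes, 267 were higher in med16 and 186 lower, 117 and 8 in med8, and 130 and 12 in elp2. The probes were chosen as low in the Col-0 libraries that enter the comparison, which favours higher values in the mutants. Of the 201 probes that were higher in med8 at 2 dpi, 169 were also higher in med16, where independent lists would share 4.36. At 4 dpi med16 shared 237 of its higher probes with med8 and 254 with elp2, against 16.1 and 18.2. The Col-0 libraries are shared here too, and med16 and med8 also share arrays, which med16 and elp2 do not. At 4 dpi the covariance of the med16 and med8 fold changes was 0.0948, against 0.0150 simulated with no effect. Their correlation was 0.492. Noise alone gave 0.728, which is no baseline for a correlation in data with effects.

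Along the change of Col-0 at 1 dpi, measured over the 6508 probes that changed 2-fold there, upper leaves of Col-0 moved by a slope of 0.273 ± 0.00151 at 2 dpi and 0.347 ± 0.002 at 4 dpi (n = 3). Upper leaves of med16 moved by 0.295 ± 0.0214 and 0.521 ± 0.0267. For med8 the slopes were 0.262 ± 0.00574 and 0.368 ± 0.00742, and for elp2 0.219 ± 0.00248 and 0.365 ± 0.00212. The Col-0 slopes share the Col-0 0 dpi libraries with the axis and the mutant slopes do not, so the tests against Col-0 are of limited weight (exact permutation p = 0.1, the smallest possible, for med8 and elp2 at both times and med16 at 4 dpi, and 0.3 for med16 at 2 dpi). Each library was set against the 0 dpi library of its replicate number, a pairing that the correlations did not support in Col-0, and med16 replicate 1, whose 0 dpi library stood apart, had the lowest med16 slope at both times (0.272 and 0.492).

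**Figure D4:**
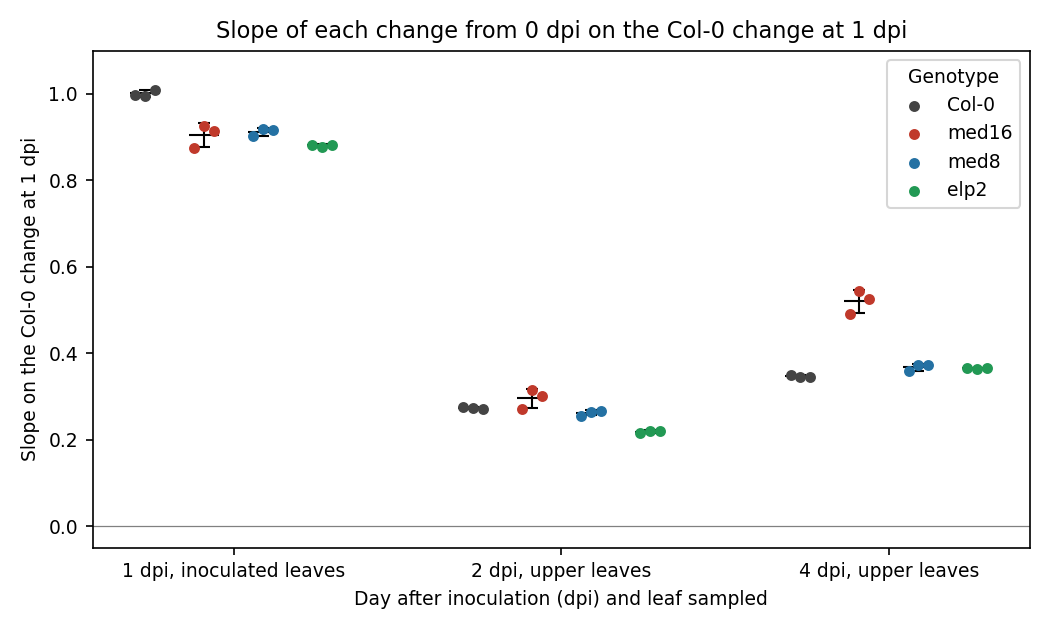
Points are the slope (y axis) of each library's change from the 0 dpi library of its genotype and replicate on the mean Col-0 change at 1 dpi, over 6508 probes, by day and leaf (x axis). Colours mark genotypes and black bars the mean ± SD. At 4 dpi med16 lies between 0.492 and 0.544 and Col-0 between 0.345 and 0.349.

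Tested as a difference from Col-0 in the mean change of 2 and 4 dpi against 0 dpi, 1324 probes changed at least 2-fold more upward in med16 and 749 more downward, 454 and 90 in med8, and 491 and 225 in elp2. In the deposited values the largest downward difference was again that of A_84_P310613 in med16 (-9.73 log2, SE 0.91, adjusted p = 3.94e-11). A_84_P867721 was also induced less in med16 (-5.50, SE 0.569, adjusted p = 4.61e-10). Without the med16 0 dpi library of replicate 1 both were still called (adjusted p = 2.47e-18 and 5.82e-23), but the other 2 libraries lay below the background limit, and against that limit the differences are no more negative than -7.99 for A_84_P310613 and -4.51 for A_84_P867721. In that fit A_84_P867721 was also induced less in elp2 (-1.55, adjusted p = 4.26e-15) and in med8 (-0.982, adjusted p = 9.23e-07). The elp2 level at 0 dpi lay below the limit. Of the 454 upward differences in med8, 378 were shared with med16, against 18.1 for independent lists. Part of that excess may come from the Col-0 libraries and from the arrays that med16 and med8 share.

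At any size, 6791, 4327 and 8403 probes were called at 2 dpi in med16, med8 and elp2, 12381, 5490 and 9152 at 4 dpi, and 9571, 4385 and 9197 for the difference of the responses. Without the 0 dpi array with med16 and med8 of replicate 1, the 2-fold counts for the difference of the med8 response were 471 upward and 161 downward. With only the compared groups in the fit, med8 had 2773 at 2 dpi and 3361 at 4 dpi, and without the array block elp2 had 5349 and 6068. Scaling to the spike-in spots raised the higher share of the calls at 2 dpi to 81.0% of 4432, 79.5% of 1902 and 64.5% of 3018. At 4 dpi it was 56.5% of 9108, 82.8% of 2663 and 78.8% of 3925, and for the difference of the responses 71.9% of 6432, 75.3% of 1720 and 87.5% of 6108. As deposited these shares lay between 45.3% and 52.2%. At least 2-fold, the scaled counts at 2 dpi were 982 higher and 223 lower in med16, 280 and 70 in med8, and 293 and 129 in elp2. At 4 dpi they were 1525 and 1145, 518 and 64, and 566 and 54, and for the difference of the responses 1767 and 404, 492 and 64, and 868 and 94.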

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

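The tests on single patterns named here as explanations of the spike-in spots were chosen after the result was seen, except that on spots of different brightness; the count of other splits was planned. The change from 0 dpi differed between a mutant and Col-0, by an interaction test, in 11153 probes for med16, 3115 for med8 and 9861 for elp2 in inoculated leaves, and in 9571, 4385 and 9197 in upper leaves. In 40 drawn splits, the real one included, in which genotypes were exchanged within each time, only the real split called as many probes in 5 of these 6 tests (1 of 40). The highest other counts were 10053 for med16 and 9818 for elp2 at 1 dpi. In upper leaves they were 4905, 2733 and 6229 for med16, med8 and elp2. Splits that mix genotypes place the differences between genotypes in the spread within groups, which lowers their counts. The rank of the real split therefore cannot exclude chance. It also says nothing on variation between plants if the replicates share pooled RNA. The count of 9818 lay close to the real 9861; splits that mixed genotypes at each time called at most 279 probes for med16 and 4 for elp2 at 1 dpi, and 1, 1 and 5 in upper leaves. For med8 at 1 dpi 4 of the 40 gave as many, the highest other 3426, so chance cannot be excluded by this count either. The 3 others all kept the libraries of a genotype together at a time point, where the difference between genotypes stays in the split, which is a structure of the samples; among splits that mixed genotypes at each time the highest count for med8 was 1.

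For the comparisons of 3 samples with 3, the 10 splits are too few for a share under 0.05. In each, 1 split, the real one, had the highest count. Every other split mixes the 2 groups, which places their difference in the spread within groups and lowers its count. The low counts of the other splits therefore cannot exclude chance. The real splits of Col-0 at 1, 2 and 4 dpi against 0 dpi called 16747, 12178 and 13378 probes and the highest others 0, 4 and 0. For med16 against Col-0 at 0, 1, 2 and 4 dpi the real splits called 6320, 12988, 6791 and 12381 and the highest others 14, 128, 0 and 0. For med8 they called 5450, 4216, 4327 and 5490 against 3, 1, 0 and 0, and for elp2 9618, 9797, 8403 and 9152 against 36, 766, 646 and 3. For med16 against med8 at 1 dpi they were 15554 and 2632, in samples that share arrays. Among the 3 other splits that part as many same-numbered pairs as the real one, the highest count was 111, for elp2 at 1 dpi.

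The spike-in spots, which the comparisons do not use, were brighter in the med16 libraries at 1 dpi, by 0.756 log2 over all libraries of the same dye and by 0.702 over Col-0 at 1 dpi. An effect of the arrays as the whole source is argued against by the med8 libraries on the same 3 arrays, from which med16 differed by at least 0.336; those libraries were themselves at 0.279, above Col-0 at 0.0536, so a part shared on these arrays stays open. A distortion of a range of brightness is argued against by the 10 spots, which differ in brightness and of which the lowest offset was 0.621. A smaller share of plant messenger RNA in the labelled RNA, for example through fungal RNA or loss of plant RNA, stays open as a hypothesis: the offset of 0.702 is of the kind it predicts, but no RNA yield and no fungal probe was analysed here. As a biological source, the genotype stays open and untested. The med16 0 dpi library of replicate 1, which stood apart in its induced probes, also had a high offset (0.516). In replicates 2 and 3 of that group the offsets were -0.0397 and 0.105. Brighter spots were thus not confined to inoculated med16 leaves.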

How the results depend on the processing

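The alternatives with spike-in scaling, with the replicate block within pairs of times and without an array were chosen after seeing the data. Counts of called probes stayed within 1.5 times their value for all 22 comparisons without the dye term, without the variance trend, without the 8286 dimmest probes, without the 0 dpi array of med16 and med8 in replicate 1 and with each library left out in turn (0.772 to 1.07 times, 186 values). Quantile normalization moved no value by more than 0.0267 log2 and tests nothing here; averaging the probes of a gene and the gene lists were not run. The replicate block changed the counts by 0.985 to 1.08 times (16997 for Col-0 at 1 dpi, 4549 for med8 at 1 dpi) and changed no call of the named probes. The block within 0 to 1 dpi and within 2 to 4 dpi gave 6412 for med8 at 1 dpi and 4862 for its response at 1 dpi. Without the array block, elp2 had 5349 at 2 dpi and 6068 at 4 dpi, where it shares arrays with Col-0. With only the compared groups, and so fewer samples, med8 had 1234, 2773 and 3361 at 1, 2 and 4 dpi. Spike-in scaling moved 13 counts: at 0 dpi to 3026 (med16), 2312 (med8) and 5650 (elp2); at 1 dpi to 28595 (med16) and 25880 (med16 against med8); at 2 dpi to 4432, 1902 and 3018; at 4 dpi to 2663 (med8) and 3925 (elp2); in the response at 1 dpi to 23262 (med16); and in the upper-leaf response to 1720 (med8) and 6108 (elp2). It also turned A_84_P802547 and A_84_P569474 in med16 at 1 dpi to -0.2504 and -0.2969, and the response of A_84_P802547 in med16 to -0.03912; these follow from its shift of the median of all probes, -0.702 and, for the response, -0.625. Among pairs of a named probe and a comparison, calls were lost in 8 of 136 under this scaling, 3 without the dye, 2 with only the compared groups, 1 without the array block and 12 of 1158 with a library left out. Only pairs called in the fit of all 48 samples were followed, so calls gained are not counted. Leaving out the med16 0 dpi library of replicate 1 lowered the SE of A_84_P867721 in Col-0 at 1 dpi from 0.464 to 0.11. The 2-fold totals stayed within 1.5 times in each alternative except 5 under spike-in scaling. Taken by direction, 24 of 44 of these counts moved further under that scaling, 2 of 44 without the 0 dpi array (med8 at 0 dpi to 145 higher, upper-leaf response of med8 to 161 downward) and 1 of 372 with a library left out (med8 at 1 dpi to 108 lower without Col-0 replicate 1). Probes outside the 84.2% above background in some group carry little information.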

Other observations

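Some differences between genotypes were present at all 4 times. In med16, 52 probes were at least 2-fold lower and 11 at least 2-fold higher than in Col-0 at all 4 times, in elp2 8 and 20, and in med8 1 and 4. Independent lists would give under 0.01 of a probe in each case (at most 0.0055, for the lower probes of med16). Over the 4 times together, 2362 probes were higher and 2411 lower in med16 at some time, of which 236 went both ways. The counts were 630, 414 and 49 in med8, and 816, 441 and 47 in elp2.

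At least 2-fold changes against 0 dpi numbered 4445 at 4 dpi in med16, 2569 in med8, 2910 in elp2 and 3163 in Col-0.

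Of the tests on the pattern of the med16 upper leaves, that on admixture was set before its result was seen and that on a stronger wild type response after. Admixture of inoculated-leaf RNA as the only source of the med16 change from 0 dpi is argued against. The 748 probes that rose by over 3 log2 in med16 at 1 dpi gave a median share of 14.1%. That share would lower a probe by at most 0.22 log2 (mixture limit -0.219). The 218 probes that fell by over 3 log2 had a median of -2.63 ± 0.0666 at 4 dpi (n = 3). The test did not subtract the fall that upper leaves of Col-0 also show. Over the 3447 probes that fell 2-fold in Col-0 at 1 dpi, the mean at 4 dpi was -0.744 in Col-0 and -1.04 in med16. The test therefore cannot decide whether admixture adds to the excess of med16 over Col-0. A stronger form of the wild type response in upper leaves stays open: over 5913 probes the med16 and Col-0 changes at 4 dpi correlated at 0.603, neither below the 0.3 set to argue against it nor with the slope over 1 set to support it (0.775). A change particular to med16, the biological source that the design names, remains possible, was not tested apart from these explanations, and was found on the same data.

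Of the tests on the med16 0 dpi library of replicate 1, that on carry-over from inoculated leaves was set before its result was seen, and the others after. Its 16 raised probes were higher by a median of 3.53 log2. Bright spots of the array in both dyes are argued against by the med8 library of the same array, where the median of these probes was 0.178. Carry-over of RNA from inoculated leaves of another genotype is a candidate explanation: of 23 probes silent in the other 2 replicates and above 14 log2 in inoculated elp2 leaves, 95.7% were raised, at a median share of 0.806% and up to 23.9%, and so were 27 of 30 for Col-0, 25 of 28 for med8 and 18 of 27 for med16 itself. Infected med16 tissue cannot be told apart from it, since 2 of the 16 probes exceeded the brightest med16 group by over 1 log2, against that source but fewer than the 50% set to exclude it, nor can upper leaves, for which 1 of only 2 probes bright in inoculated leaves alone (50%) was raised.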
